A study of Drosophila melanogaster with 3 samples.

How the data were processed

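The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Drosophila melanogaster prepupae, with a labelled age of 2 days. The flies carried a transgene that expresses the protein Eagle (gene eg) fused to green fluorescent protein, and an antibody against the tag was used for the precipitation. Per the labels, chromatin was sheared by sonication. There were 3 biological replicates in 1 group, numbered as in the labels, so no comparison between conditions could be made. The spread between replicates is given as an SD beside some values. No test uses this spread: the tests take peaks or genes as units, so their p-values do not cover variation between replicates.

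The deposited files were peak lists on the dm6 assembly, per the labels. For each replicate there was a list of ranked peaks and a shorter list that had passed a threshold on the irreproducible discovery rate (IDR), which measures how well peak ranks agree between a pair of analyses. For the series there were further lists of both kinds, and the authors call 1 of the thresholded lists conservative. Per the deposited descriptions, replicate lists were derived from the alignments of that replicate alone and series lists from the alignments of all 3 replicates. Support of a series peak by a replicate list is therefore not independent evidence. The aligner, the peak caller and their versions are not given in the sources used here.

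The signal value of each peak is the authors' own peak strength, on a scale of its own in each list, and was used to describe, rank or filter peaks. The deposited score is a whole number derived from the IDR, and the lowest score in the thresholded lists corresponds to an IDR of 0.01. The −log10 of the q-value was deposited for each peak and was looked at but enters no test. The files hold no read counts, so the sequencing depth of each replicate is unknown and no interval that needs it is given. Intervals on shares of peaks or genes cover counting error only, and neighbouring peaks and genes are not independent. In the ranked series lists, 32 further columns of values for individual members were not used, because nothing ties them to a replicate. A control experiment named in the labels was not analysed here.

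Peaks on 2L, 2R, 3L, 3R, 4 and X were used, which left out 1 of 9370 conservative peaks. Genes came from Ensembl release 115 (assembly BDGP6 version 6.54) and sequence from the RefSeq copy of release 6 of the genome, which is dm6. Every peak lay within the chromosome lengths, and annotated start codons read ATG in that sequence. Transposon genes were left out. A summit within 500 bp of any annotated transcription start site (TSS) was called a promoter summit. Other summits were assigned in order to 5′ UTR, coding exon, 3′ UTR, intron and intergenic, and a class for exons of non-coding genes was added after the design had been fixed. Shares were compared with 1000 random placements within the same chromosomes by two-sided empirical p-values, whose smallest value is 0.002.

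Peaks of different lists were called shared if they overlapped by at least 1 bp, with 1000 random placements and a one-sided p. A protein-coding gene had a promoter peak if a conservative summit lay within 1000 bp of any of its TSSs. Each of 33 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over the lists, and log2 odds ratios were computed after adding 0.5 to each count. For 15 entries an older symbol was replaced by the current one, and 3 of 385 entries had no match. Each of 16 motifs was counted on either strand in 101 bp at the summit and in a window of that size 300 bp away on a random side, and compared by a two-sided exact McNemar test with Benjamini-Hochberg adjustment. One motif, TGACTCA, is the reverse complement of TGAGTCA and checks strand handling. The reversed string of each motif was the control for base composition, which is void for strings that read alike backwards. It is also void for CACACACA, whose reverse is the same repeat shifted by 1 base. Signal at promoter and other summits was compared by a two-sided permutation test of medians with 100000 resamples. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

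The genes named are the nearest to the 20 conservative peaks of highest signal among those overlapped in all 3 replicates, then eg, kni and knrl, and, per list, the 3 genes whose promoter peak had the highest signal with up to 3 genes without one, in alphabetical order. The groups, lists, motifs, tests, naming rule and most alternatives were fixed before the data were examined. The peak lists were then explored before the final computation. That exploration included 10 searches for short sequences. Leaving out each replicate was added after the data had been seen for the peak counts, the overlap and the correlation. Alternatives used other thresholded lists, peaks overlapped in all 3 replicates, the stronger part of the list, other overlap rules, other distances and windows, matched random gene lists and other sequence controls. Placement tests under alternatives used 100 placements.

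The procedures were tested on simulated data. All 40 planted lists of 20 genes, with 12 or more bound, were recovered, and 2% of 200 random lists were called. None of the 16 motifs was called at random sites, and a motif planted at 3% of summits was recovered with a gain of 3.07 percentage points. Bound genes were drawn without regard to gene length, TSS number or neighbours, and random sites lack the base composition of summits. These rates therefore need not hold for the real lists and motifs. Copying part of one random list into another gave 52.1% shared peaks. One pair of random peak lists shared 2.69% of peaks with a p of 0.0396, which is below the usual threshold. After that value had been seen, 20 further random pairs were drawn, and 0 of these had a p under 0.05, with a median p of 0.604. The first value was kept.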

Results

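Binding of Eagle was mapped in whole prepupae by ChIP-seq of the tagged protein. Eagle is an orphan nuclear receptor of the knirps family, known from the development of serotonergic neurons. The data are 3 biological replicates of 1 group. The thresholded list of replicate 1 held 6215 peaks, that of replicate 2 held 6024 and that of replicate 3 held 7476 (6572 ± 789 peaks, SD, n = 3). The conservative list of the series held 9370 peaks, with a median width of 360 bp. Read depth is unknown.

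The first question was whether the same sites were found in each replicate. The peak upstream of Ugalt, a gene for a sugar nucleotide transporter, had the highest signal of the conservative list and was overlapped in all 3 replicates. Between replicates, 63.8% to 81.0% of peaks were shared, with a mean of 72.5% over 6 directed comparisons. Random placement shared 2.56% on average and at most 3.79%. The one-sided empirical p was 0.001 for each comparison, the smallest that the placements allow. Of 9369 conservative peaks, 4105 (43.8%) were overlapped in all 3 replicates, 1854 in 2, 1873 in 1 and 1537 (16.4%) in none. A single replicate overlapped 63.7% ± 6.06 of them (SD, n = 3).

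Replicate support followed signal. Part of this order is built in, because the series list and its signal draw on the alignments of all 3 replicates. With peaks ranked by signal in 10 classes of 936 or 937, 99.1% of the strongest class were overlapped in all 3 replicates, against 1.92% of class 3 from the bottom. The weakest class stood apart from this order, with 16.8%. Across conservative peaks found in both members of a pair, the rank correlation of the authors' signal was 0.829 between replicates 1 and 2, 0.757 between 1 and 3, and 0.824 between 2 and 3. These correlations run across peaks, which are not independent replicates. They cover only peaks that passed the IDR threshold in the series list and in both replicate lists. The IDR measures agreement of ranks, so this choice of peaks may raise them.

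**Figure D1:**
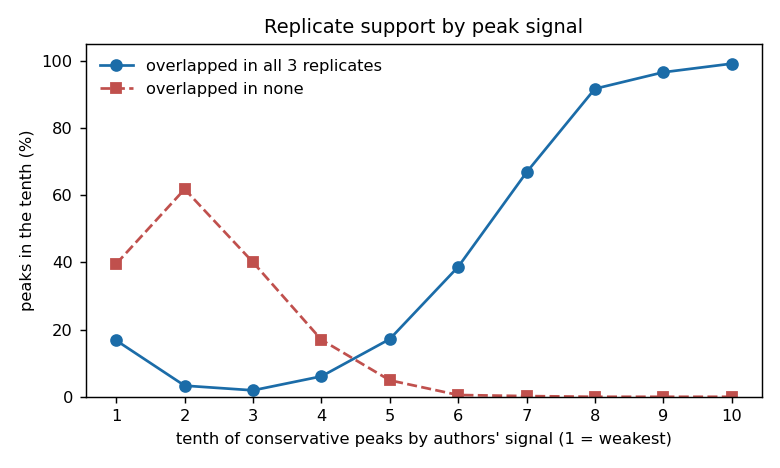
Share of conservative peaks overlapped by a peak in all 3 replicate lists (circles) or in none (squares), in percent, for 10 classes of peaks by the authors' signal (1 is the weakest). The share in all 3 is 99.1% in the strongest class and 16.8% in the weakest.

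The eg gene itself (FBgn0000560, 3L 21808703 to 21817600, forward strand) had a promoter peak. It lay at 3L 21808289 to 21808521 with its summit 302 bp upstream of the TSS, a signal of 558 (rank 592 of the list) and support in all 3 replicates. The replicates' own signals there were 194, 196 and 173. Within 20 kb of eg there were 5 conservative peaks. Of these, 2 other peaks found in all 3 replicates lay at the promoters of CG32448 and Nopp140, and the remaining 2, the stronger with a signal of 68.4, were in no replicate list. The related gene kni, a gap gene of the embryo, had 1 peak, 44 bp downstream of a TSS, with a signal of 73.3 and no replicate support. At knrl, the third family member, no summit lay within 1000 bp of the TSS. Within 20 kb of knrl there were 7 peaks, and 2 of these lay in its intron and were found in all 3 replicates, at 3L 20600765 to 20600926 (signal 223) and 3L 20612885 to 20613244 (signal 167).

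**Figure D2:**
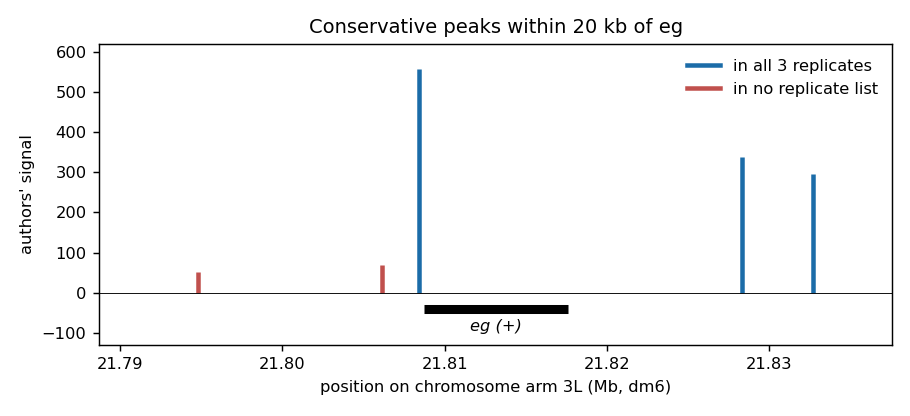
Conservative peaks within 20 kb of eg, by position on 3L (Mb, dm6) and authors' signal; the black bar is the gene. The tallest peak, with a signal of 558, is 302 bp upstream of the TSS.

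Among the 20 strongest peaks found in all 3 replicates, 14 were promoter summits, 3 were intronic, 2 intergenic and 1 in an exon of a non-coding gene inside osa. Signals ran from 2214 to 3996. The peak of Ugalt (FBgn0024994) was at X 2703714 to 2704058, 38 bp upstream of the TSS, with replicate signals of 1431, 1146 and 1454. The peak of mRpL41 (2R 15217591 to 15217913, signal 3019), a mitochondrial ribosomal protein gene, had its summit 135 bp upstream. The summits of mRpS10 (signal 2521) and PNPase (signal 2988), a gene for an RNA-degrading enzyme, were 128 and 85 bp upstream. Further promoter peaks of this set lay at CG14100, CenG1A, CG18549, Tcs5, CG7601, ph-p, CG3552, the small heat shock gene Hsp27 (signal 2218, 151 bp upstream) and the ribosome biogenesis gene eIF6 (signal 2214, 103 bp upstream). The summit assigned to eEF1gamma was 5.73 kb from it, near the start of a long non-coding RNA gene. Intronic or intergenic peaks of the set were nearest to CG11050, CG16753, CG32772, CG31668 and CG13323.

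The location of summits was compared with random positions. Promoters held 3580 of 9369 summits, or 38.2% (95% Wilson interval 37.2 to 39.2), against 13.5% of random positions, a ratio of 2.82. Introns held 44.6% against 39.5%. Coding exons held 0.523% against 13.6%, 3′ UTRs 0.811% against 4.43%, and intergenic sequence 14.0% against 27.3%. Each of these had a permutation p of 0.002 over random placements (adjusted p = 0.0028), the smallest possible. In the replicates' own lists the promoter share was 39.5% ± 2.29 (SD, n = 3). For 5′ UTRs (1.00% against 0.781%) the adjusted permutation p was 0.0186, but the replicate lists held 0.726% ± 0.179, and non-coding exons did not pass the test (permutation p = 0.579).

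Promoter summits made up 62.0% of the 100 strongest peaks (95% Wilson interval 52.2 to 70.9) and 36.9% of the weaker part of the list (35.6 to 38.3). Over all peaks the median signal was 141 at promoters and 134 elsewhere (permutation test of the difference, p = 0.00749). This difference depended on the definition: with a 200 bp promoter window it was -0.261 (permutation p = 0.939). In peaks overlapped in both replicates 2 and 3 (without replicate 1) it was 2.87 (permutation p = 0.613). It was 20.7 in peaks overlapped in both replicates 1 and 3, 19.0 in both 1 and 2, and 21.2 in fully supported peaks. In the stronger peaks it was 15.2, and in the other series lists 13.6 to 19.8 (permutation p at most 0.00122 for all of these). The sets by replicate all contain the fully supported peaks and keep the signal of the series list, so they do not show that the difference hangs on replicate 1. In the thresholded lists of replicates 1, 2 and 3, each with its own signal, promoter summits were higher by 5.02, 2.02 and 2.99. The direction was thus seen in each replicate's list, but these differences were not tested.

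**Figure D3:**
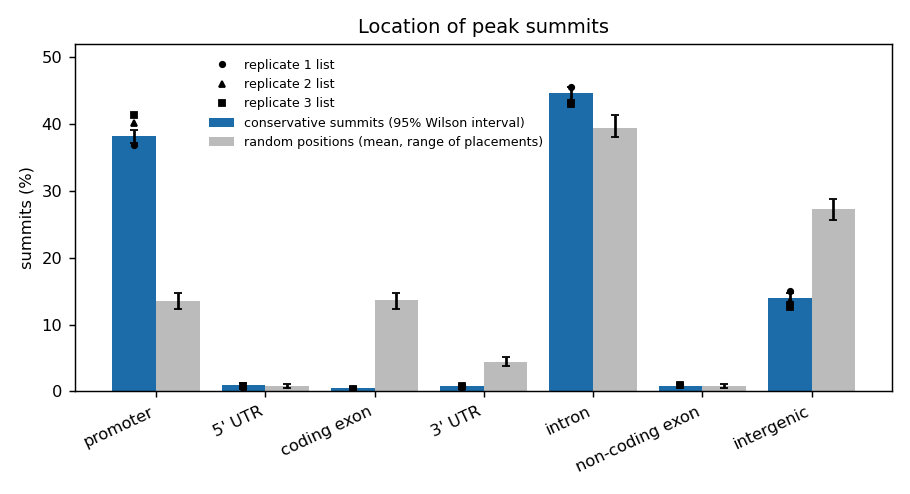
Percent of summits in each annotation class for the conservative list (blue, 95% Wilson interval), the 3 replicate lists (black symbols) and random positions (grey, mean with the range over placements). Promoters hold 38.2% of summits and 13.5% of random positions.

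Of 13945 protein-coding genes, 3800 (27.2%) had a promoter peak, here a summit within 1000 bp of a TSS rather than the 500 bp of promoter summits. In the replicates' own lists there were 3080 ± 267 such genes (SD, n = 3), and 2150 genes were among them in all 3 lists and the conservative one. Restricting the conservative list to peaks overlapped in both other replicates gave 2437 genes without replicate 1, 2258 without replicate 2 and 2239 without replicate 3. Of the 33 gene lists, 8 differed from the remaining genes at an adjusted p under 0.05, 5 with more promoter peaks and 3 with fewer. At an unadjusted p under 0.05 there were 13. The 80 protein-coding genes of chromosome 4, which had no thresholded peak, were counted as genes without one. Among them are the list members ci (Hedgehog and Dpp), ey (neuronal temporal factors) and apolpp (fat body).

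Regulators of the response to ecdysone, the steroid hormone of metamorphosis, had a promoter peak in 15 of 18 genes (83.3%, 95% Wilson interval 60.8 to 94.2; Fisher's exact test, adjusted p = 1.24e-05). In the replicate lists the share was 75.9% ± 8.49 (SD, n = 3). The highest signals were at tai (724), a coactivator of the ecdysone receptor, Eip93F (655; 3R 21972191 to 21972436, 82 bp upstream of a TSS) and Eip75B (416; 3L 17999671 to 17999924, 59 bp downstream of a TSS), each in all 3 replicates. The tai summit lay in an intron, 968 bp upstream of a TSS. Hr39, Kr-h1 and svp had none. Against random lists matched on TSS number and gene length, which had 57.5% on average, the call was lost (adjusted permutation p = 0.125). Ecdysone effector and steroidogenesis genes had a promoter peak in 4 of 21 (exact adjusted p = 0.628), with the highest signals at Ldh (564), Eip63E and ImpL2. None of 11 glue protein genes had one, with a 95% Wilson upper limit of 25.9% (27.3% if 3 of 11 is taken as the limit for a count of 0; exact adjusted p = 0.108).

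Ribosomal protein genes had promoter peaks in 67 of 92 (72.8%, 95% Wilson interval 63.0 to 80.9; exact adjusted p = 3.18e-18), with 61.2% ± 6.55 in the replicate lists (SD, n = 3). The highest signals were at RpS19b (1320), RpL34b (770) and RpL7 (625), and RpL10, RpL10Aa and RpL13A had none. The RpS19b summit lay 917 bp upstream of a TSS, in sequence classed as intron. Mitochondrial ribosomal protein genes had 25 of 73 (exact adjusted p = 0.282), although mRpL41, mRpS23 and mRpS10 had some of the strongest peaks. That of mRpS23, 382 bp upstream, is the same peak as that of CenG1A, whose TSS is nearer (110 bp). Against matched lists, which had 14.6%, that share was higher (adjusted permutation p = 0.0044). Proteasome genes had 9 of 32 (exact adjusted p = 0.872), with Rpn3 highest (signal 412).

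Promoter peaks were also more frequent in 3 signalling and patterning lists. Notch pathway and E(spl) genes had 11 of 19 (57.9%, exact adjusted p = 0.0335), led by numb (522), fng (286, intergenic, 748 bp upstream) and mam (224). Wnt pathway genes had 11 of 18 (61.1%, exact adjusted p = 0.0175), led by the kinase gene sgg (739), nkd (565) and the receptor gene fz2 (467, intronic, 814 bp downstream). Appendage and wing patterning genes had 11 of 20 (55.0%, exact adjusted p = 0.040), led by Dll (624), salr (320) and bi (219). Delta, arm and ap had no promoter peak. Against matched lists the Notch list was still called (adjusted permutation p = 0.0319), and the Wnt and appendage lists were not (adjusted permutation p = 0.589 and 0.882). Of 12 alternatives, the Notch call was kept in 7 and the Wnt and appendage calls in 4 each; without replicate 2 the exact adjusted p was 0.133, 0.862 and 0.134, without replicate 3 it was 0.127, 0.850 and 0.145, and without replicate 1 the Wnt value was 0.108. The log2 odds moved little for the Notch list (1.86, and 1.64 and 1.65 without replicate 2 or 3) and the appendage list (1.70, and 1.53 and 1.54), and more for the Wnt list (2.04, and 0.68 and 0.70). These alternatives keep only peaks found in both other replicates and so fewer genes, and a lost call does not show that a list depends on the replicate left out.

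Promoter peaks were fewer than among the remaining genes in 3 gene families. Odorant and gustatory receptor genes had 3 of 119 (2.52%, exact adjusted p = 1.45e-11), at Gr32a, Or88a and Gr97a, with summits 772, 813 and 554 bp upstream. Cytochrome P450 genes had 8 of 85 (9.41%, exact adjusted p = 5.96e-04), led by Cyp6u1 (463). Cpr cuticle protein genes had 9 of 70 (12.9%, exact adjusted p = 0.0335), led by Cpr62Ba (325, intronic, 772 bp upstream). This Cpr call was lost against matched lists (adjusted permutation p = 0.615) and kept in 3 of 12 alternatives. It was lost without replicate 1, 2 or 3 (exact adjusted p = 0.208, 0.306 and 0.177; log2 odds -1.08, -0.94 and -1.19 against -1.28), and the cytochrome P450 call without replicate 2 (exact adjusted p = 0.0564; log2 odds -1.51 against -1.78).

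**Figure D4:**
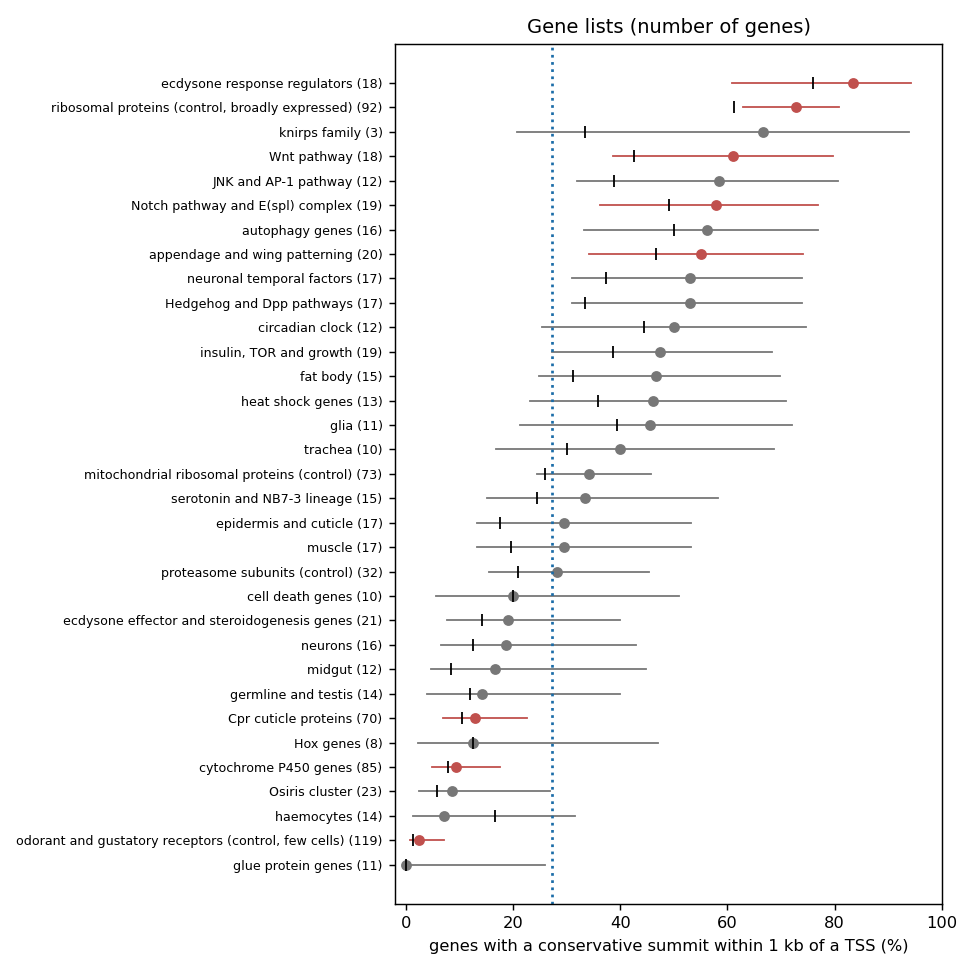
Percent of genes with a promoter peak per list (points, 95% Wilson interval), with the number of genes in brackets; red marks an adjusted p under 0.05, black ticks the mean of the 3 replicate lists and the dotted line the 27.2% of all genes. Ecdysone response regulators reach 83.3% and receptor genes 2.52%.

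The remaining lists did not pass the threshold in the main test. Hedgehog and Dpp genes had 9 of 17 (exact adjusted p = 0.0723), with shn (668), Mad (425) and tkv highest. Neuronal temporal factors had 9 of 17 (exact adjusted p = 0.0723), with hb (1236), mamo (928) and Syp (908). JNK and AP-1 genes had 7 of 12 (exact adjusted p = 0.0723), autophagy genes 9 of 16 (exact adjusted p = 0.072) with Atg2 (539) and Atg7 (508), and growth and insulin genes 9 of 19 (exact adjusted p = 0.149). Clock genes had 6 of 12 (exact adjusted p = 0.208), heat shock genes 6 of 13 (exact adjusted p = 0.241), cell death genes 2 of 10, Osiris genes 2 of 23 (exact adjusted p = 0.136) and Hox genes 1 of 8. The knirps family had 2 of 3 (exact adjusted p = 0.282). The list for serotonin and the NB7-3 lineage, where eg is known to act, had 5 of 15 (exact adjusted p = 0.685), with nkd, Ddc (100) and ttk highest and no promoter peak at dan, danr or en.

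Marker lists of cell types did not differ from the remaining genes in the main test. Neuron markers had 3 of 16 (exact adjusted p = 0.685), at elav (936), Rbp9 (307) and para (76.7, in no replicate list), and were lower than matched lists (adjusted permutation p = 0.0224). Glia markers had 5 of 11, with moody (1227) and loco (647). Muscle markers had 5 of 17, with sls (577) and Mef2 (206), and epidermis and cuticle markers 5 of 17. Fat body markers had 7 of 15, trachea markers 4 of 10, midgut markers 2 of 12, germline and testis markers 2 of 14, and haemocyte markers 1 of 14. These counts are of the conservative list. Some genes counted, such as the trachea markers kni and verm, had no promoter peak in any replicate list. The trachea marker dysf had one in all 3 replicate lists but none in the conservative list. Whole animals hold all of these tissues, so the lists name no source of the signal.

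Sequence at summits was compared with sequence 300 bp away. The knirps-family half-site TAGAGCA, written from memory of the site for Kni, was in 0.736% of summit windows and 0.747% of control windows (log2 ratio -0.02, exact adjusted p = 1). Of the 16 motifs, 7 differed. TATTTAT (9.55% against 6.90%, log2 ratio 0.47, exact adjusted p = 6.79e-10), GAGAGAG (3.71% against 2.66%, exact adjusted p = 1.94e-04) and the DNA replication-related element TATCGATA (0.651% against 0.320%, exact adjusted p = 0.00485) were more frequent at summits. CACACACA, CAGCTG, CACGTG and AGGTCA, the nuclear receptor half-site (1.76% against 2.27%, exact adjusted p = 0.0348), were less frequent than 300 bp away. The direction depended on the comparison: against shuffled sequence the log2 ratio was 2.17 for CACACACA and 1.12 for CAGCTG, and against windows 1000 bp away it was 0.18 for CACACACA. Of 12 alternatives, the direction and call were kept in 12 for TATTTAT, 10 each for CAGCTG and CACGTG, 9 for CACACACA, 7 for TATCGATA and 4 each for GAGAGAG and AGGTCA. GAGAGAG turned in 6, with log2 ratios of -0.0091, -0.45 and -0.55 without replicate 1, 2 or 3 (exact adjusted p = 1, 0.0438 and 0.0113). Alternatives without a replicate keep only peaks found in both other replicates. The AGGTCA call was lost in 8, with an exact adjusted p of up to 0.845, and among them without replicate 1, 2 or 3 (0.112, 0.715 and 0.629). The TATCGATA call was lost in 5 (exact adjusted p up to 0.163), among them without replicate 3 (0.116). CACGTG lost its call in 2 (exact adjusted p up to 0.351), and CAGCTG (0.263) and CACACACA (0.0597) lost theirs in 1 each besides the turns above. Over the 12 alternatives the log2 ratio was 0.50 to 3.04 for TATCGATA, -1.01 to -0.36 for CACGTG and -0.75 to -0.03 for AGGTCA. These 3 motifs thus kept their sign where the call was lost.

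Of the reversed control strings 6 of 14 also differed, leaving out GAGAGAG and TATTTAT, which read alike backwards and so have no such control. Among the 6 was the reverse of AGGTCA, which was also lower at summits. The reverse of CACACACA, also among the 6, is the same repeat shifted by 1 base and so is no control either. The reversed AP-1 strings among the 14 are reverse complements of each other and stand for the same sequence. Summit windows were 62.7% A and T, against 56.8% at 300 bp. The GAGAGAG result reversed with replicate support: in peaks found in all 3 replicates it was in 2.05% of summit windows and 3.02% of control windows (exact McNemar p = 0.00569), and in peaks found in 1 replicate in 6.25% and 2.35%. Of these 1873 peaks, 1069 were found only in replicate 3 (8.33% against 2.99%, exact McNemar p = 4.01e-08). Those found only in replicate 2 had 4.43% against 1.56%, and only in replicate 1 2.62% against 1.43% (exact McNemar p = 0.0347 and 0.332). TATTTAT was higher at summits of peaks found in all 3 replicates (11.8% against 6.48%), and not of those found in none (6.57% against 7.42%, exact p = 0.395). In the weakest of 5 signal classes it was lower at summits (5.02% against 7.95%, exact McNemar p = 2.63e-04). CACACACA, CAGCTG and CACGTG were less frequent at summits of peaks found in all 3 replicates (log2 ratio -0.93, -0.81 and -1.04). In peaks found in fewer the ratios were -0.15, -0.10 and -0.17 (exact McNemar p = 0.284, 0.498 and 0.579). Within these, peaks found in 2 replicates had -0.02, -0.41 and -0.43 (exact McNemar p = 0.120 for CAGCTG and 0.430 for CACGTG). The difference between the classes was not tested for these motifs.

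**Figure D5:**
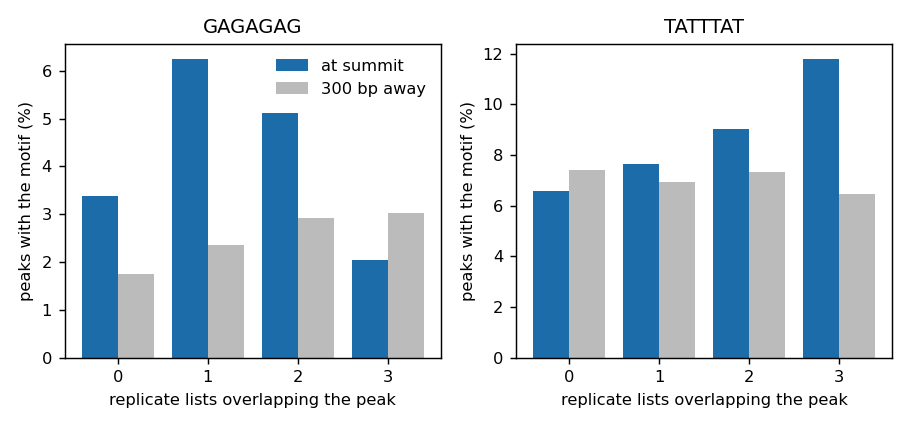
Percent of conservative peaks with GAGAGAG (left) or TATTTAT (right) in the summit window (blue) and 300 bp away (grey), by how many replicate lists overlap the peak. GAGAGAG is at 2.05% of summits in peaks found in all 3 replicates and TATTTAT at 11.8%.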

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

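Alternatives listed before the data were examined are reported with those added later, which left out a replicate for the peak counts, the overlap and the correlation. Of 78 values for the main results, 60 kept their direction, call or size. A count was called kept within 1.5 times the main count, so fully supported peaks were called kept although they fell from 4105 to 2758 at 50% reciprocal overlap. The promoter share kept its direction under every alternative run, with 27.1% to 49.1%. The overlap is a percentage and has no direction to lose. Its values without a replicate reuse comparisons of the main test, so they count as kept by construction. Where a value moved, the cause was not tested, except that some alternatives hold fewer peaks or wider windows by construction. Read depth is unknown, so what it limits could not be assessed.

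The mean count per replicate was 1040 at or above the median conservative signal, a value from a list on another scale, and 61633 in the ranked lists. With a replicate left out, the correlation was 0.757 to 0.829. Each of these is the value of the remaining pair, already given in the main result, and so is no further test. Genes with a promoter peak numbered 2062 in fully supported peaks, 2450 in the stronger peaks, 6889 at 5000 bp and 2239 to 2437 with a replicate left out. Lists called were 8 in the main test and 5 in each of the other series lists, 5 in fully supported peaks, 6 in the stronger peaks, 3 to 6 with a replicate left out, 8 at 500 bp, 9 at 5000 bp, 11 in gene bodies and 6 against matched lists. Ribosomal protein and receptor genes were called under all 12. Calls were also gained, with adjusted p for glue genes of 0.00647 at 5000 bp and 0.016 in gene bodies. Autophagy genes gave 0.0431, 0.0282 and, in fully supported peaks, 0.0353, Hedgehog and Dpp genes 0.00325 in gene bodies and Osiris genes 0.0431 at 5000 bp. Against matched lists, mitochondrial ribosomal genes (0.0044) and neuron markers (0.0224) were gained. Motifs called fell from 7 to 3 in 51 bp windows. The signal difference at promoters was -0.261 with a 200 bp window and 2.87 to 20.7 with a replicate left out.

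The sign of the log2 odds of 12 lists, none of them called in the main test, turned under some alternatives. Serotonin and NB7-3 lineage (0.48) gave -1.04 in the stronger peaks, -0.15 at 5000 bp, -0.68 against matched lists and -0.19 to -0.047 with a replicate left out (-0.062 between). Cell death genes (-0.35) gave 0.63 in the list of 11724, 1.13 in the list of 8252, 0.76 in fully supported peaks, 0.46 in the stronger peaks, 0.54 in gene bodies and 0.47 to 0.62 with a replicate left out (0.61 between). Hox genes (-0.91) gave 1.16 in the list of 11724, 0.28 in the list of 8252, 0.035 at 5000 bp, 1.20 in gene bodies and -1.85 to 0.049 with a replicate left out. Hedgehog and Dpp pathways (1.58) gave -0.11 in fully supported peaks and -0.25 to 0.66 with a replicate left out. JNK and AP-1 pathway (1.87) gave -0.41 in fully supported peaks and -0.57 to 0.17 with a replicate left out (-0.55 between). Neurons (-0.53) gave 0.47 in the list of 11724 and 1.24 in gene bodies. Muscle (0.23) gave -0.45 in the list of 8639, -0.40 in the list of 8252, -0.11 in fully supported peaks, -0.40 in the stronger peaks, -1.18 against matched lists and -0.26 to 0.19 with a replicate left out (-0.25 between). Fat body (1.24) gave -0.047 to 0.54 with a replicate left out. Haemocytes (-1.75) gave 0.37 in the list of 11724. Epidermis and cuticle (0.23) gave -0.026 in the list of 11724, -0.45 in the list of 8639, -0.40 in the list of 8252, -0.11 in fully supported peaks, -0.40 in the stronger peaks, -0.45 at 5000 bp, -0.28 in gene bodies, -0.032 against matched lists and -0.39 to -0.25 with a replicate left out (-0.26 between). Trachea (0.89) gave -0.14 in fully supported peaks, -0.43 in the stronger peaks and -0.42 to 0.61 with a replicate left out (-0.28 between). Proteasome subunits (0.11) gave -0.55 in fully supported peaks, -0.092 in the stronger peaks and -0.71 to -0.28 with a replicate left out (-0.42 between). Log2 ratios turned for 8 motifs, of which GAGAGAG, CAGCTG and CACACACA were called in the main test. Control windows were drawn anew for each list. TAGAGCA (-0.021) gave 0.22 in the list of 11724, 0.044 in the list of 8252, 0.14 in fully supported peaks (-0.042 with the control windows of the whole list), 0.27 in the stronger peaks, 0.047 in 51 bp windows, 0.0099 in the widest windows and -0.26 to 0.11 with a replicate left out. GAGAGAG (0.48) gave -0.055 in the list of 8252, -0.50 in fully supported peaks, -0.28 in the stronger peaks and -0.55 to -0.0091 with a replicate left out (-0.45 between). GGTCACACT (0.87) gave -0.23 to 0.36 with a replicate left out (-0.09 between). CAGCTG (-0.38) gave 1.12 against shuffled sequence. CACACACA (-0.45) gave 2.17 against shuffled sequence and 0.18 against windows 1000 bp away. TGTTTAC (-0.17) gave 0.13 against shuffled sequence and 0.028 against windows 1000 bp away. CTTATCA (0.19) gave -0.017 against windows 1000 bp away. TGATAAT (0.31) gave -0.50 against shuffled sequence. Of motifs not called in the main test, TGATAAT was higher and called in 6 alternatives (0.47 to 0.88, lowest adjusted p 3.90e-04) and GGTCACACT in 4 (1.17 to 3.42, 5.19e-08). CAGGTAG (-0.81 in the list of 11724, 0.0116) and ACCGGTT (-1.31 in the stronger peaks, 0.0303) were lower and called in 1 each.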

Other observations

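The tests on GAGAGAG and chromosome 4, the test on mitochondrial ribosomal and proteasome genes, the genes with most peaks and the short-sequence search were chosen after the values had been seen. Genes with many conservative summits are named by raw count, which was not corrected for gene length and not tested. The gene sbb had 39 summits in 79.1 kb, 20 of these in all 3 replicates, and kirre had 34 in 394 kb, or 0.863 per 10 kb. The gene shn, a regulator in Dpp signalling, had 29 in 58.3 kb. The ecdysone-induced genes Eip75B and Eip74EF had 27 and 23, of which 10 and 7 were found in all 3 replicates. On the 5 large arms, peaks per Mb ranged from 64.9 on 3R (95% exact Poisson interval 62.1 to 67.7) to 78.9 on X (75.3 to 82.6), with 73.8 on 3L.

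Short sequences of 7 bases with at most 4 A or T were ranked on 2L, 2R and X, and the first 10 were tested on 3L and 3R. Of these, 6 passed an adjusted p of 0.05. All 6 contain CAGTG or its reverse complement CACTG, so they are not separate results. AACACTG and ACACTGT, which also contain CACTG, did not pass (exact McNemar test, adjusted p = 0.555 and 0.0844). CCTACAA turned, from 0.902% of summit windows against 0.345% where it was ranked to 0.553% against 0.842% where tested (exact McNemar test, adjusted p = 0.164). The earlier 10 searches had used all chromosomes, so this split is no independent test. CAGTGCA was in 2.57% of 4156 tested summit windows and 1.80% of control windows (exact McNemar test, adjusted p = 0.0379), and CACTGTA in 1.47% and 0.842% (adjusted p = 0.0377).

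The promoters of broadly expressed genes may be recovered whatever factor is tagged. Pooled ribosomal, mitochondrial ribosomal and proteasome genes had a promoter peak in 51.3% of 197 genes, against 26.9% of other genes (Fisher's exact test, p = 6.70e-13), which goes with that explanation. Mitochondrial ribosomal and proteasome genes alone had 32.4% (95% Wilson interval 24.2 to 41.8; Fisher's exact p = 0.228), below the 72.8% of ribosomal protein genes. Mitochondrial ribosomal genes still had more than matched lists (34.2% against 14.6%, adjusted permutation p = 0.0044), so the excess is not shown to be limited to ribosomal protein genes. General accessibility of promoters stays open, since no control precipitation was analysed. No biological explanation was tested, because the design has 1 group.

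GAGAGAG was higher at summits over all peaks and lower in peaks found in all 3 replicates. The summit minus control difference was 3.62 percentage points higher in peaks found in fewer than 3 lists than in the others. This restates the split that prompted it, so it does not show where the gain belongs, which stays open. Signal alone predicted 2.68 of these points with support shuffled within 5 classes of signal (permutation p = 0.00521) and 2.88 within 50 classes (permutation p = 0.0204), so low signal goes with most of the difference. Whether it goes with all of it is not decided, because support rises steeply with signal and signal still varies within each class. Without peaks found only in replicate 3, the motif was still in 4.17% of summits against 2.22% (exact McNemar p = 3.31e-07), so peaks found only there are not the whole source. The peaks kept include some found in replicate 3 and another replicate, and the series list drew on all 3 replicates. Replicate 3 as a source is therefore not excluded. Whether peaks with GAGAGAG are sites of the tagged protein stays open, and no biological explanation was tested.

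Chromosome 4 had no conservative peak, where its length predicts 94.3. The ranked lists held 14, 3 and 3 peaks there in replicates 1, 2 and 3, at most 1.94% of the number its length predicts, which argues against peaks lost only at the threshold. The density was 10.4 per Mb in replicate 1 (95% exact Poisson interval 5.68 to 17.4), below the 68 to 221 per Mb at the centromere-side ends of the other arms. In replicate 3 it was 2.23 (0.459 to 6.50) against 14 to 146. Replicate 2 had the same 2.23 on 3 peaks against 6 to 75, where the interval reaches the lowest end, so low density as at these ends is argued against by replicates 1 and 3 and not by replicate 2 alone. Peaks in every ranked list also exclude removal of the whole chromosome before calling. Partial filtering and low mapping stay open as possible explanations, and no biological explanation was tested.

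The 5 peaks within 20 kb of eg were more than at 53.8% of 779 genes of similar length, whose median was 4, so an effect of extra transgene copies cannot be told apart from ordinary density, because the value lies between the bounds set for either. The lowest share of peaks common to 2 replicates, 63.8%, lay above every random placement (at most 3.79%).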
